A study of Rattus norvegicus with 12 samples.

How the data were processed

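Hippocampal RNA of 12 rat samples was analysed, 6 labelled NC and 6 labelled AS3h. Per the labels' protocols, RNA was purified with a HiPure Universal kit and 1.3 µg of total RNA per sample went into strand-specific libraries made with a VAHTS Universal V10 kit. The submitters' processing notes name FastQC 0.11.5, STAR and the rat build mRatBN7.2, without saying what each was used for. The counting program, its strand setting, the annotation and any filters are not given in the sources used here. Genes that overlap or share near-identical copies can therefore share reads.

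The deposited values were on a log2 scale, 1 library per file and 23760 genes in each. From the values, each deposited log2 value was the log2 of 1 plus a read count divided by 1 factor per library. Whole read counts came back in 100% of the values (within 0.02 read), and gave the library totals. How the authors derived the deposited library factors is not given in the sources used here. They ranged from 0.92 to 1.16, and median-of-ratios factors recomputed from the recovered reads from 0.881 to 1.11. All 12 files were matched to their samples through the sample records, and groups and replicate numbers came from the titles.

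The design fixed before the data were examined assumed counts. Because the deposited unit was log2, its stated fallback for normalised values was used: limma 3.58.1 in R 4.3.3, with a robust empirical Bayes fit and a trend on mean level, applied to the deposited log2 values. Genes were kept where the normalised value was at least 1 in at least 6 libraries, which left 19050. The model held the group only, with no replicate block. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Fold changes are on the log2(value + 1) scale and understate the change of genes with few reads. Library measures were compared by two-sided exact permutation tests. Counting error sets the floor of the low genes, and limits stated in reads cover counting error only.

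28 gene lists were fixed before the data were examined: cell type markers, inflammatory and stress programmes, neuronal activity, the clock, and markers of blood and adjoining tissue. Symbols with no row were not analysed here, and some genes were in more than 1 list. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation, with which none of the 6 lists called passed. The directional test fry called 6 lists, 4 of them shared with camera (microglia, immediate early, glucocorticoid and clock); it called the hypoxia and heat shock lists and not the choroid plexus and mitochondrial lists. Member counts are given over all genes tested and adjusted over the list alone. Genes named by the fixed rule were Ccr3, the 10 genes with the largest change in each direction among those past the threshold with a mean normalised value of at least 1 and a symbol that was not a placeholder, and up to 4 members of each list past the threshold by smallest p, or 2 where none passed. Exceptions are marked, and some genes that the rule names are not reported here.

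Alternatives planned before the data were examined were limma-voom with sample quality weights on the recovered reads, other filters, a pseudocount of 0.1, a replicate block, leaving out each library, other thresholds, an estimated correlation and fry. Added after the data were seen were other library factors, leaving out AS3h 4 and AS3h 5, and blood and choroid plexus covariates. Replicate libraries were compared pairwise, and the closest pair differed by a chi-square of 11.9 per degree of freedom, so no library was counted as deposited again. The steps were tested on simulated data for AS3h against NC, with 19286 genes tested. At a mean of at least 100 reads, 87% of genes changed 1.5-fold and 96% of genes changed 2-fold were recovered. Of 193 calls, 5.18% were unchanged genes. Each gene was simulated independently, so variation that genes share within a library was not covered. Recovery of genes with fewer reads, Ccr3 among them, was not tested. A gene table of another assembly, GRCr8, was used for genomic spans by symbol only, and no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.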

Results

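RNA sequencing was carried out on rat (Rattus norvegicus) hippocampus, the medial temporal brain region needed for spatial and episodic memory, in 2 groups of 6 samples labelled NC and AS3h. The series concerns cognitive impairment after prolonged underwater operation and names the chemokine receptor gene Ccr3 in its title. No sample with a Ccr3 knockdown was among the 12 analysed here, so the 1 comparison was AS3h against NC. The labels do not expand either abbreviation. Reads assigned to genes ranged from 29.6 M (AS3h 3) to 38.1 M (NC 2) per library, with means of 35.1 ± 2.91 M in NC and 32.7 ± 2.45 M in AS3h (SD, n = 6 each; two-sided exact permutation p = 0.147). At these depths 3 reads corresponded to a CPM of 0.0787 to 0.101. Values below are normalised read counts as mean ± SD with n = 6 per group, and log2FC is the log2 fold change, AS3h over NC, ± its standard error. No label states that the samples came from separate animals, so the p-values measure the spread between these samples.

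Among gene lists fixed beforehand, glucocorticoid-responsive and activity-dependent genes were higher in AS3h hippocampus and microglial markers were lower. The clock list was higher in its mean, with 8 of 17 genes higher and 2 lower. Camera with its preset correlation and fry called these 4 lists, and camera with an estimated correlation called none of them. Of 19050 genes tested, 960 were higher and 804 lower in AS3h at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 4737 had an unadjusted p under 0.05. Most changes were small: the median absolute log2 fold change of the 1764 genes was 0.36, and 92 were higher and 41 lower by at least 2-fold. Mt1, which encodes a metal-binding metallothionein, rose from 21.1 ± 3.93 to 109 ± 17.7 (log2FC 2.32 ± 0.17, adjusted p = 1.53e-05). Maff, a small Maf transcription factor, rose from 30.4 ± 5.56 to 172 ± 76.2 (log2FC 2.37 ± 0.24, adjusted p = 6.2e-05). The count of changed genes fell to 1029 without NC 2, to 1091 without AS3h 4 and to 861 without both AS3h 4 and AS3h 5, the libraries with the most choroid plexus reads. It was 758 with the mean levels of blood and choroid plexus markers as covariates, under which 36 of the 74 genes other than Ccr3 that the naming rule picked past the threshold did not pass. Of the 1764 genes, 532 stayed called in the same direction, and the log2 fold changes of all 1764 were a median of 1.003 times those without covariates.

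Most of the largest fold increases were in genes with few reads in NC. Igfbp1, which encodes an insulin-like growth factor binding protein, had 21 reads over the 6 NC libraries, 4 of them at 0, and 245 reads in AS3h (log2FC 4.13 ± 0.66, adjusted p = 0.00178). Tcp11 had 28 and 240 reads (log2FC 4.05 ± 0.71, adjusted p = 0.00322), and Stpg3 had 35 and 168 (log2FC 2.65 ± 0.53, adjusted p = 0.00666). Tcp11 was at 0 in 4 NC libraries but at 4.51 (log2) in NC 3, against 4.50 in AS3h 4. Stpg3 was at 0 in 1 NC library and at 4.17 in NC 3, against 4.04 in AS3h 2. Serpina16 (5 and 72 reads), Nanos2 (5 and 65), Prr30 (5 and 46) and Pfkfb1 (15 and 63) also rose, with log2 fold changes of 3.03, 2.78, 2.57 and 2.39. Of the genes in this paragraph, only Igfbp1 and Nanos2 had all 6 AS3h libraries above every NC library. With the blood and choroid plexus covariates Tcp11, Stpg3, Serpina16, Prr30 and Pfkfb1 did not pass (adjusted p = 0.0566 to 0.172), at log2 fold changes of 3.68, 2.61, 2.68, 2.74 and 2.25. Pfkfb1 also lost its call with the replicate number as a block (adjusted p = 0.0515), without AS3h 4 and AS3h 5 (0.0725) and in 6 of the 12 omissions of 1 library. Because 1 was added before the log, these values understate the change of genes with few reads.

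Rgs13, a regulator of G-protein signalling, fell from 172 ± 25.2 to 55.3 ± 30.05 (log2FC -1.77 ± 0.27, adjusted p = 0.00131). Tnfsf10, which encodes the death ligand TRAIL, fell from 148 ± 33.5 to 49.7 ± 10.02 (log2FC -1.55 ± 0.18, adjusted p = 0.00018). Kcnh5, a voltage-gated potassium channel gene, fell from 106 ± 31.5 to 35.9 ± 14.7 (log2FC -1.56 ± 0.27, adjusted p = 0.00262). Lipg, encoding endothelial lipase, and Hpgds, encoding hematopoietic prostaglandin D synthase, fell with log2 fold changes of -1.89 and -1.41. Klf8 fell by 2.07 on the log2 scale, and the low-count genes Serpinb8, Pigz and Cyp11b2 fell by 2.80, 2.61 and 2.17 (adjusted p = 0.00391, 0.0497 and 0.0376). Pigz and Cyp11b2 lost their calls with a pseudocount of 0.1 (adjusted p = 0.0754 and 0.056), and Pigz also with total-read factors, no filter and the replicate block. Klf8, Pigz and Cyp11b2 lost theirs in 10, 9 and 8 of the 12 omissions of 1 library. Without AS3h 4 and AS3h 5 these 3 and Hpgds did not pass (adjusted p = 0.0688 to 0.165). A row for Rpl13a, a ribosomal protein gene, fell from 551 to 29 reads and was at 0 in 5 of 6 AS3h libraries. Another row with the same symbol stood at 8061 in NC and 7401 in AS3h (log2 fold change -0.13 ± 0.07, adjusted p = 0.284). Whether the rows share reads was not tested. With the covariates Lipg, Kcnh5, Hpgds, Pigz, Cyp11b2 and the smaller Rpl13a row did not pass (adjusted p = 0.0713 to 0.217), at log2 fold changes of -1.43, -1.24, -1.13, -2.60, -2.29 and -4.00.

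Ccr3, the eotaxin receptor gene named in the series title, rose from 24.8 ± 5.36 to 60.4 ± 32.2 normalised reads (log2FC 1.15 ± 0.28, adjusted p = 0.0192), a 2.21-fold difference with all 6 AS3h libraries above all 6 NC libraries. The gene had 162 reads over the NC libraries and 371 over the AS3h libraries. Of 17 chemokine and chemokine receptor genes tested, 2 rose, 0 fell and 15 did not pass, with the same count adjusted over the list alone. The other was Ccl3, encoding the macrophage inflammatory protein 1 alpha, at 3.54 ± 3.36 in NC and 12.3 ± 3.49 in AS3h (log2FC 1.96 ± 0.55, adjusted p = 0.0372). Ccl3 lost its call in 8 of the 12 omissions of 1 library, with no filter (adjusted p = 0.0503), the replicate block (0.0707) and a pseudocount of 0.1 (0.0849), and without AS3h 4 and AS3h 5 (0.0769). The list as a group did not pass (camera adjusted p = 0.727), its median being -0.02 and its mean 0.09. The list mean of AS3h 2 was 5.96 against 4.83 to 5.18 in the other AS3h libraries, and without AS3h 2 the Ccr3 log2 fold change was 0.92. With the means of the blood cell and choroid plexus markers as covariates, Ccr3 had a log2 fold change of 0.84 and an adjusted p of 0.206.

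Among 26 cytokine genes and targets of the inflammatory transcription factor NF-kB, 1 rose, 0 fell and 25 did not pass, as when adjusted over the list alone (camera adjusted p = 0.592). Il1r1, the interleukin-1 receptor gene, was the one that rose, from 94.9 ± 33.8 to 234 ± 81.5 (log2FC 1.30 ± 0.25, adjusted p = 0.00585). With the blood and choroid plexus means as covariates it was at 1.23 (adjusted p = 0.0835). The log2 fold changes of Il1b and Il6 were 0.39 ± 0.80 and -1.28 ± 0.62 (adjusted p = 0.817 and 0.213). They were picked after their values were seen. In the interferon and antigen presentation list of 25 genes, Ifi27 rose (log2FC 1.19 ± 0.10, adjusted p = 3.71e-05), Mx2 fell (log2FC -0.47 ± 0.12, adjusted p = 0.027) and 23 did not pass, the same count as adjusted over the list alone (camera adjusted p = 0.636). Mx2 did not pass with the covariates (-0.59, adjusted p = 0.0696), without AS3h 4 and AS3h 5 (0.0737) or in 5 of the 12 omissions of 1 library.

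**Figure D1:**
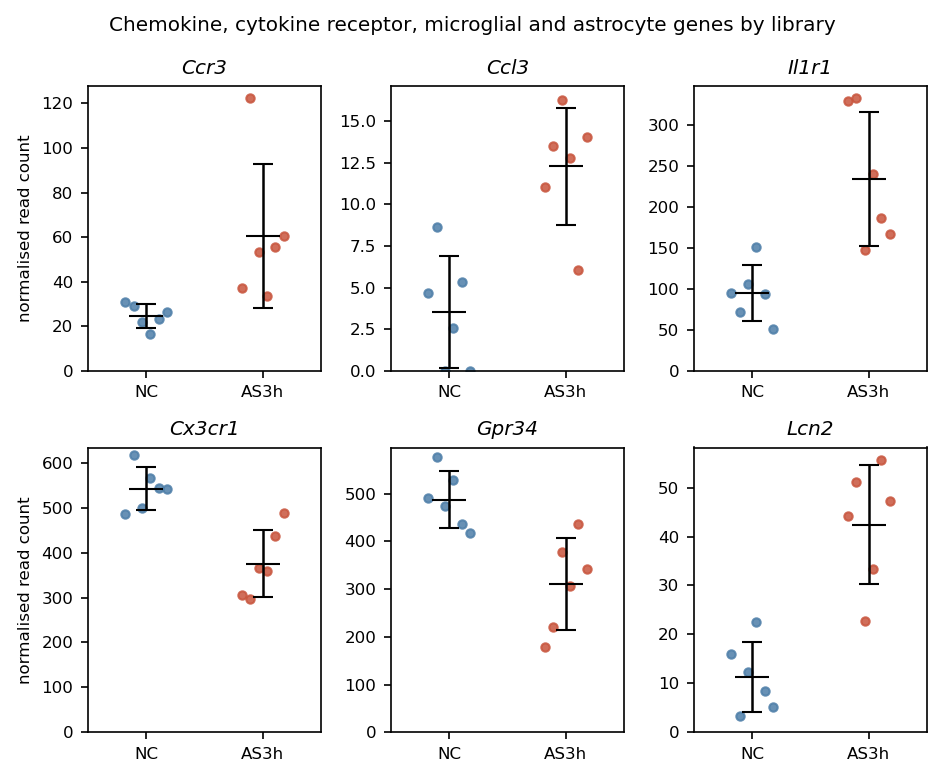
Normalised read counts of Ccr3, Ccl3, Il1r1, Cx3cr1, Gpr34 and Lcn2 in each library (points; 6 NC and 6 AS3h), with the mean (horizontal mark) and SD (bars). Ccr3 averaged 24.8 in NC and 60.4 in AS3h, with all AS3h points above all NC points, while Cx3cr1 and Gpr34 were lower in AS3h.

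Microglial markers were lower in AS3h as a group (camera adjusted p = 0.00039; adjusted p = 0.367 with an estimated correlation), with a mean log2 fold change of -0.24 over 24 genes. Of these, 2 fell, 0 rose and 22 did not pass. Adjusted over the list alone, 7 fell and 1 rose. Cx3cr1, the fractalkine receptor gene, fell from 542 ± 47.4 to 375 ± 74.8 (log2FC -0.55 ± 0.12, adjusted p = 0.00883). Gpr34, a microglial lysophosphatidylserine receptor gene, fell from 488 ± 59.2 to 310.38 ± 96.6 (log2FC -0.71 ± 0.18, adjusted p = 0.0257). With the blood and choroid plexus means as covariates, Cx3cr1 and Gpr34 were at -0.59 and -0.73 (adjusted p = 0.059 and 0.0734). Gpr34 also lost its call with the replicate block (adjusted p = 0.0565) and in 3 of the 12 omissions of 1 library. Among 20 genes of the disease-associated microglia programme, Lgals3 (log2FC 1.02 ± 0.27, adjusted p = 0.0265) and Ctsb (log2FC 0.12 ± 0.036, adjusted p = 0.0451) rose and Ctsz fell (log2FC -0.39 ± 0.11, adjusted p = 0.0417), the same 3 as adjusted over the list alone. With the covariates Lgals3 was at 0.55 (adjusted p = 0.387) and Ctsb at 0.11 (adjusted p = 0.22). All 3 lost their calls with the replicate block (adjusted p = 0.0636 to 0.0887) and without AS3h 4 and AS3h 5 (0.0558 to 0.147). Lgals3, Ctsb and Ctsz lost theirs in 4, 11 and 10 of the 12 omissions of 1 library, Ctsz also with no filter and Ctsb with recomputed factors. The list did not pass (camera adjusted p = 0.735; median -0.02, mean 0.06). None of 9 border macrophage and alternative activation markers passed under limma, over all genes or adjusted over the list alone. The smallest p values belonged to Arg1 (log2 fold change -0.38, adjusted p = 0.0795) and Lyve1 (0.36, adjusted p = 0.468).

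Immediate early genes, which neurons transcribe within minutes of activity, were higher in AS3h. Of 28 tested, 12 rose, 0 fell and 16 did not pass. Adjusted over the list alone, 17 rose and 1 fell. Fosb rose from 159 ± 34.4 to 458 ± 61.7 (log2FC 1.54 ± 0.14, adjusted p = 5.09e-05) and Fos from 135 ± 26.7 to 320.03 ± 78.9 (log2FC 1.22 ± 0.17, adjusted p = 0.000587). Egr4 rose from 391 ± 70.2 to 758 ± 128 (log2FC 0.96 ± 0.13, adjusted p = 0.00057), and Junb from 943 ± 123 to 1575 ± 234 (log2FC 0.73 ± 0.11, adjusted p = 0.000758). The list was higher with camera's preset correlation (adjusted p = 1.89e-09; adjusted p = 0.249 with an estimated correlation), and 7 of its genes rose with the covariates.

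Genes that respond to glucocorticoid hormones were also higher. Of 25, 13 rose, 0 fell and 12 did not pass. In all, 15 rose adjusted over the list alone (camera adjusted p = 1.54e-10; adjusted p = 0.358 with an estimated correlation). Besides Mt1, they included Fkbp5, a co-chaperone of the glucocorticoid receptor (log2FC 0.87 ± 0.12, adjusted p = 0.000525), Tsc22d3, encoding the glucocorticoid-induced leucine zipper protein (log2FC 0.64 ± 0.12, adjusted p = 0.0052), and Plin4, a lipid droplet gene (log2FC 1.28 ± 0.23, adjusted p = 0.00337). With the blood and choroid plexus means as covariates 2 of the 25 genes passed and the list mean was 0.45 (camera adjusted p = 3.62e-05). Tsc22d3 was then at 0.46 (adjusted p = 0.101) and Plin4 at 1.10 (adjusted p = 0.0649). Il1r1 belonged to this list as well as to the cytokine list.

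Clock genes changed in both directions. Of 17 circadian genes, 8 rose, 2 fell and 7 did not pass. Adjusted over the list alone, 10 rose and 3 fell (camera adjusted p = 0.00141; adjusted p = 0.249 with an estimated correlation). Among alternatives, 6 rose and 0 fell with the replicate block, 7 and 0 without AS3h 5, 6 and 0 without AS3h 4 and AS3h 5, and 4 and 1 with the covariates. The negative-limb genes Per2 (log2FC 0.68 ± 0.06, adjusted p = 3.71e-05), Per1 (log2FC 0.53 ± 0.087, adjusted p = 0.00206) and Cry2 (log2FC 0.35 ± 0.051, adjusted p = 0.000846) rose, as did the output gene Tef (log2FC 0.34 ± 0.056, adjusted p = 0.00219). The 2 that fell were Arntl, which encodes the clock activator BMAL1 (log2FC -0.23 ± 0.062, adjusted p = 0.0311), and Npas2 (log2FC -0.37 ± 0.10, adjusted p = 0.0407). The clock list members Dbp and Nr1d1 had log2 fold changes of 0.17 ± 0.074 and 0.10 ± 0.083 (adjusted p = 0.167 and 0.499). Arntl, Npas2, Dbp and Nr1d1 were picked after their values were seen. The labels give no time of sampling, so a difference in hour between the groups was not tested.

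**Figure D2:**
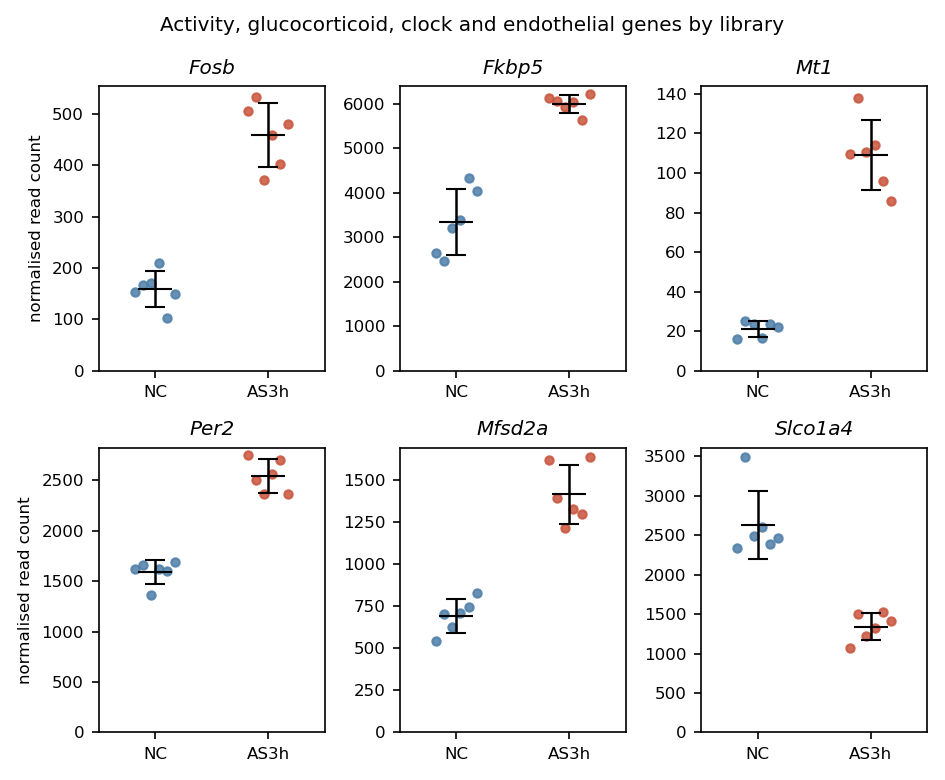
Normalised read counts of Fosb, Fkbp5, Mt1, Per2, Mfsd2a and Slco1a4 in each library (points; 6 NC and 6 AS3h), with the mean (horizontal mark) and SD (bars). All 6 AS3h libraries lay above all 6 NC libraries for the first 5 genes and below them for Slco1a4.

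Other stress lists did not pass in camera as a group, although fry called the hypoxia list (adjusted p = 0.00482) and the heat shock list (adjusted p = 0.045). Of 22 hypoxia-responsive genes, 3 rose, 0 fell and 19 did not pass, with 4 rising adjusted over the list alone (camera adjusted p = 0.0847). They included Pfkfb3, a glycolytic regulator (log2FC 0.46 ± 0.08, adjusted p = 0.00321), and Adm, encoding adrenomedullin (log2FC 0.72 ± 0.17, adjusted p = 0.0153). With the covariates Adm was at 0.46 (adjusted p = 0.257), and without AS3h 4 and AS3h 5 its adjusted p was 0.071. Of 16 heat shock and cold-inducible genes, Rbm3 (log2FC 0.43 ± 0.076, adjusted p = 0.00321), Dnajb1 (log2FC 0.34 ± 0.065, adjusted p = 0.00502) and Bag3 (log2FC 0.47 ± 0.13, adjusted p = 0.0284) rose. Chordc1 fell (log2FC -0.46 ± 0.11, adjusted p = 0.0155) and 12 did not pass. Dnajb1, Bag3 and Chordc1 did not pass with the covariates (0.24, 0.36 and -0.43; adjusted p = 0.0856, 0.261 and 0.0921), nor Bag3 in 5 of the 12 omissions of 1 library or without AS3h 4 and AS3h 5 (0.145). In all, 9 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0628). In camera this list passed with limma-voom (adjusted p = 0.0469), no filter (0.0496), the replicate block (0.0342), the covariates (0.0281) and in 3 of the 12 omissions of 1 library. The endoplasmic reticulum stress list of 20 genes split, with 3 higher, 3 lower and 14 not passing. Sesn2 (log2FC 0.58 ± 0.083, adjusted p = 0.000749) and Atf4 (log2FC 0.29 ± 0.055, adjusted p = 0.00483) rose and the chaperone-related Creld2 fell (log2FC -0.43 ± 0.085, adjusted p = 0.0063), of which Atf4 did not pass with the covariates (0.26, adjusted p = 0.0771). Adjusted over the list alone, 4 rose and 5 fell (camera adjusted p = 0.633; median -0.04, mean 0.01). Of 16 antioxidant genes, Gclc, for glutathione synthesis (log2FC 0.25 ± 0.05, adjusted p = 0.00706), and Srxn1 (log2FC 0.49 ± 0.13, adjusted p = 0.0241) rose and 14 did not pass, the same count as adjusted over the list alone (camera adjusted p = 0.633; median -0.00664, mean 0.03). Srxn1 lost its call without AS3h 4 and AS3h 5 (adjusted p = 0.0812) and in 2 of the 12 omissions of 1 library.

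Blood-brain barrier genes moved in opposite directions. Mfsd2a, the endothelial lysophospholipid transporter gene, rose from 691 ± 98.6 to 1413 ± 175 (log2FC 1.03 ± 0.10, adjusted p = 5.09e-05). Slco1a4, an organic anion transporter gene, fell from 2631 ± 430.26 to 1341 ± 174 (log2FC -0.97 ± 0.10, adjusted p = 8.64e-05). Abcb1a, encoding P-glycoprotein, fell from 2757 ± 167 to 2126 ± 91.4 (log2FC -0.37 ± 0.05, adjusted p = 0.000496). Eng also rose (log2FC 0.42 ± 0.11, adjusted p = 0.0291), but not with limma-voom (adjusted p = 0.0584), the covariates (log2 fold change 0.34, adjusted p = 0.241), without AS3h 4 and AS3h 5 (0.0634) or in 7 of the 12 omissions of 1 library. Of the 18 genes, 3 rose, 3 fell and 12 did not pass. Adjusted over the list alone, 4 rose and 6 fell (camera adjusted p = 0.848; median 0.03, mean -0.12).

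Astrocyte markers did not pass as a group. Of 15, Fgfr3 rose (log2FC 0.22 ± 0.062, adjusted p = 0.0352) and 14 did not pass, as adjusted over the list alone (camera adjusted p = 0.134). The astrocyte list passed as lower in 1 of the 12 omissions of 1 library, that of NC 1 (mean -0.087, camera adjusted p = 0.0343). Of 21 reactive astrocyte genes, Lcn2, encoding lipocalin-2 (log2FC 1.98 ± 0.38, adjusted p = 0.00502), Stat3 (log2FC 0.43 ± 0.058, adjusted p = 0.000474) and Osmr, the oncostatin M receptor gene (log2FC 1.34 ± 0.38, adjusted p = 0.0397), rose. Tm4sf1 fell (log2FC -0.70 ± 0.13, adjusted p = 0.00421) and 17 did not pass, the same count as adjusted over the list alone (camera adjusted p = 0.487). With the covariates Fgfr3, Lcn2 and Osmr were at 0.25, 1.69 and 1.41 (adjusted p = 0.11, 0.095 and 0.153). Fgfr3 and Osmr each lost their call in 8 of the 12 omissions of 1 library, and Osmr with limma-voom (adjusted p = 0.0688) and no filter (0.0541). AS3h 2 had the highest mean of that list, 7.71 against 7.04 to 7.29 in the other AS3h libraries. Of 14 oligodendrocyte markers, Aspa rose (log2FC 0.82 ± 0.23, adjusted p = 0.0436), Ugt8 (log2FC -0.37 ± 0.096, adjusted p = 0.0253) and Ermn (log2FC -0.45 ± 0.12, adjusted p = 0.026) fell and 11 did not pass (camera adjusted p = 0.829). Aspa was at 0.47 with the covariates (adjusted p = 0.356) and had an adjusted p of 0.162 with the replicate block and 0.101 without AS3h 4 and AS3h 5. Aspa, Ugt8 and Ermn lost their calls in 9, 5 and 6 of the 12 omissions of 1 library. Olig2, a lineage transcription factor gene, was the one of 9 precursor markers that fell (log2FC -0.86 ± 0.15, adjusted p = 0.00337), with 8 not passing (camera adjusted p = 0.435). With the covariates both lists were lower (camera adjusted p = 0.0145 and 0.0396). The counts of both oligodendrocyte lists were the same adjusted over the list alone.

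Neuronal lists showed single-gene changes. Of 12 excitatory markers, Slc17a7, the vesicular glutamate transporter gene, rose (log2FC 0.27 ± 0.072, adjusted p = 0.0318). Among the 2 that fell was the transcription factor gene Tbr1 (log2FC -0.39 ± 0.10, adjusted p = 0.0275), and 9 did not pass. In all, 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.957). The AMPA receptor subunit gene Gria2 fell (log2FC -0.29 ± 0.07, adjusted p = 0.0189) and the other 24 synaptic genes did not pass, as adjusted over the list alone (camera adjusted p = 0.487). With the covariates Gria2 did not pass (-0.22, adjusted p = 0.21), 4 synaptic genes rose, and the list was higher (mean 0.15, camera adjusted p = 0.000109). Gria2 also lost its call without AS3h 4 and AS3h 5 (adjusted p = 0.104). Pcp4 fell (log2FC -0.32 ± 0.089, adjusted p = 0.0351) among 17 subfield markers, 16 not passing, with 2 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.829). Slc17a7, Tbr1 and Pcp4 lost their calls in 7, 6 and 7 of the 12 omissions of 1 library and without AS3h 4 and AS3h 5 (adjusted p = 0.0617, 0.0634 and 0.137). With the covariates Tbr1 and Pcp4 did not pass (-0.31 and -0.32, adjusted p = 0.234 and 0.166), nor did Pcp4 with the replicate block (0.0707). None of 13 inhibitory neuron markers or 15 neurogenesis markers passed under limma, over all genes or adjusted over the list alone (camera adjusted p = 0.629 and 0.134). Their smallest p values belonged to Slc32a1 (log2 fold change 0.18, adjusted p = 0.299) and Cck (0.15, adjusted p = 0.331), and to Eomes (-2.05, adjusted p = 0.106) and Top2a (-0.40, adjusted p = 0.11). Eomes passed under limma in 1 of the 12 omissions of 1 library (adjusted p = 0.0399).

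Markers of adjoining tissues and of blood varied between libraries. Of 16 choroid plexus and ependymal markers, Kcne2 rose (log2FC 1.37 ± 0.33, adjusted p = 0.0205), 0 fell and 15 did not pass, as adjusted over the list alone (camera adjusted p = 0.00141; adjusted p = 0.634 with an estimated correlation; fry adjusted p = 0.222). With the covariates Kcne2 was at 0.81 (adjusted p = 0.106), but Kcne2 is itself in the choroid plexus mean, so part of this drop is built in. The list mean was 9.98 in AS3h 5, 7.61 in AS3h 4 and 6.46 in AS3h 2, against 4.46 to 6.16 in the NC libraries. Without AS3h 4 and AS3h 5 the camera adjusted p was 0.148. None of 10 blood cell markers passed under limma, over all genes or adjusted over the list alone (camera adjusted p = 0.0507). The blood list passed with recomputed median-of-ratios factors (adjusted p = 0.0482), in 6 of the 12 omissions of 1 library, and without AS3h 4 and AS3h 5 (adjusted p = 0.0146). The smallest p values were those of Alas2 (log2 fold change 0.82, adjusted p = 0.0592) and Epx (1.13, adjusted p = 0.15), and Alas2 passed with the CPM filter (adjusted p = 0.0465) and in 3 of the 12 omissions of 1 library. None of 16 mural and fibroblast markers passed either way (camera adjusted p = 0.633), with Rgs5 at -0.22 (adjusted p = 0.128) and Abcc9 at -0.32 (adjusted p = 0.295). AS3h 2 stood highest at a list mean of 10.41. Of 18 markers of neighbouring regions, Ntng1 (log2FC -0.99 ± 0.13, adjusted p = 0.00042) and Drd1, a dopamine receptor gene (log2FC -0.67 ± 0.19, adjusted p = 0.0358), fell, 0 rose and 16 did not pass, as adjusted over the list alone (camera adjusted p = 0.0847). This list passed as lower with the replicate block (camera adjusted p = 0.0398), the covariates (0.0119), without AS3h 4 and AS3h 5 (0.0415) and in 2 of the 12 omissions of 1 library. Drd1 lost its call with limma-voom (adjusted p = 0.053), the replicate block (0.0547), the covariates (log2 fold change -0.75, adjusted p = 0.0856) and in 10 of the 12 omissions.

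Mitochondrially encoded transcripts were lower as a list (camera adjusted p = 0.00681; adjusted p = 0.785 with an estimated correlation; fry adjusted p = 0.222). Mt-nd4l was the one of 12 that fell (log2FC -0.36 ± 0.093, adjusted p = 0.027), 11 did not pass, and 4 fell adjusted over the list alone. Mt-nd4l lost its call with the covariates (-0.35, adjusted p = 0.153), without AS3h 4 and AS3h 5 (0.123) and in 6 of the 12 omissions of 1 library. The share of reads on these genes was 11.03 ± 1.09% in NC and 9.78 ± 0.702% in AS3h (SD, n = 6 each; two-sided exact permutation p = 0.0368, adjusted p = 0.123 over 6 library measures). Without AS3h 4 and AS3h 5 the list no longer passed (camera adjusted p = 0.127).

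**Figure D3:**
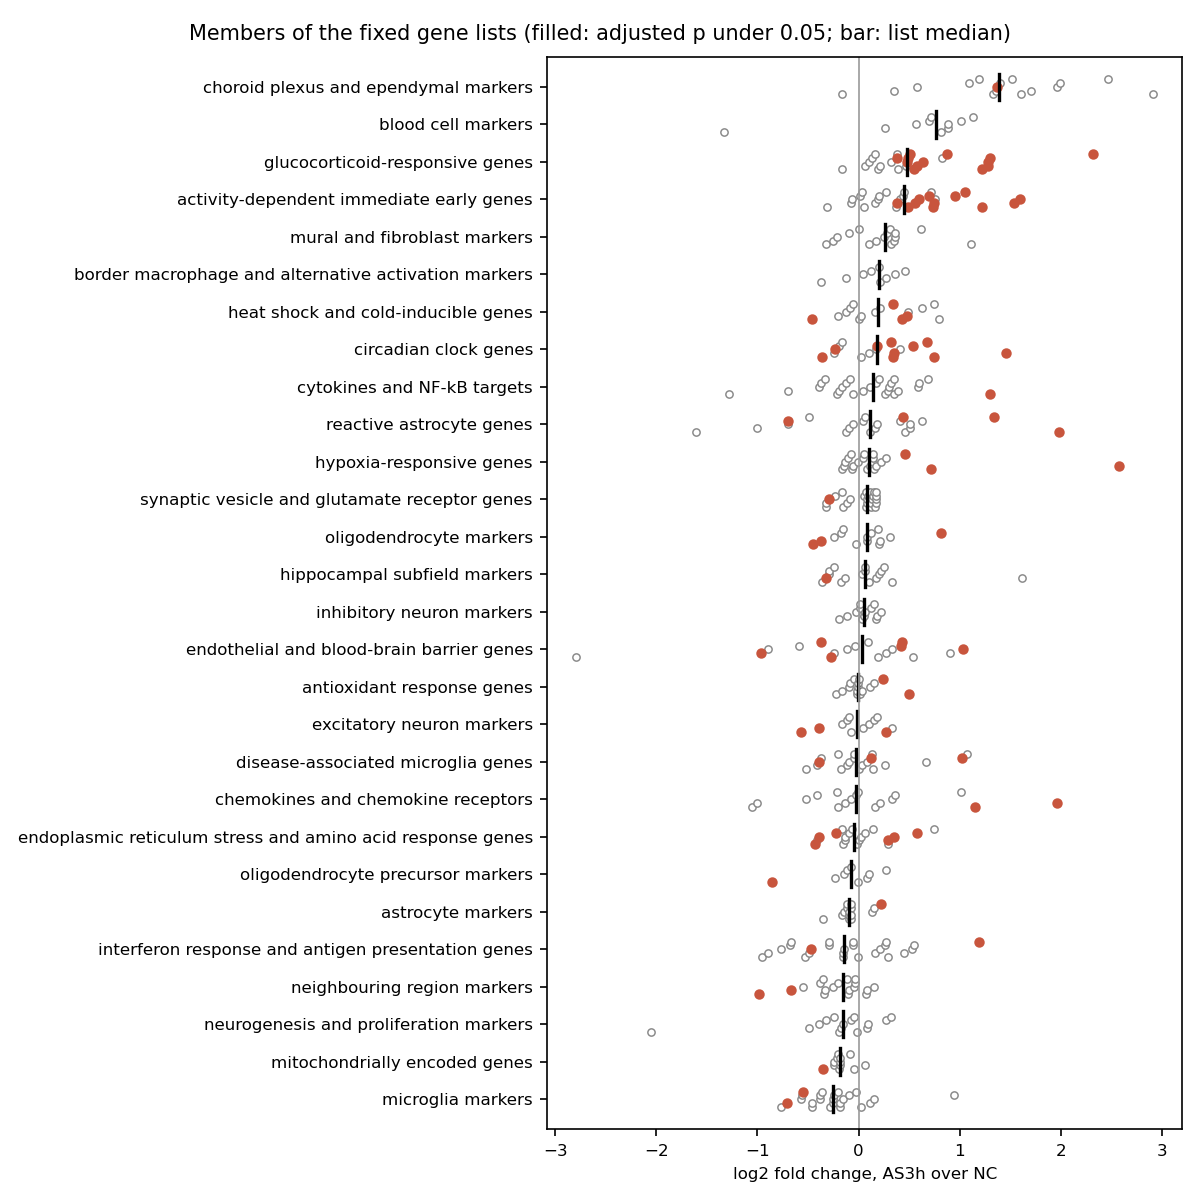
Log2 fold change, AS3h over NC, of each tested member of the 28 fixed gene lists, 1 list per row, ordered by list median (vertical bar); filled points had an adjusted p under 0.05 over all genes. The choroid plexus list had the highest median, 1.38, with 1 filled point, and 13 of 25 glucocorticoid-responsive genes were filled, all to the right of 0.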

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

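The tests of the microglial markers and of the choroid plexus genes, and the count with covariates, were chosen after the results were seen. The other tests in this part were set before their own results were seen. The covariates used in some of them were added after the data were seen. Of 232 groups of 6 values checked, 17 had a library set apart from the other 5 by more than Dixon's 95% critical value for 6 samples; chance gives this in about 1 in 20 groups, here 11.6.

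The 1764 changed genes were set against 100 of the 462 ways to divide the 12 libraries 6 and 6. The actual division was the 1 of 100 that reached this count, and the highest other gave 415. This argues against a chance division, though 100 divisions cannot show a share under 1 in 100. It does not bear on a factor shared by the samples of a group. Genes that fell had longer genomic spans (median 49.6 kb) than genes that rose (20.3 kb), and 88.8% of the changed genes had a span. In a refit on the 14468 genes with a span, 1477 of 1686 calls (87.6%) stayed after a trend with span was removed. With blood and choroid plexus means as covariates the called genes' log2 fold changes were a median of 1.003 times those without (quartiles 0.854 and 1.18). Of the 1764, 532 then stayed called in the same direction. With these means held, the called genes' log2 fold changes thus did not shrink in the median. Calling favours genes with little spread within groups, while the choroid plexus list mean varied widely within AS3h (SD 1.93, against 0.603 in NC). That choice favours a ratio near 1, so the ratio cannot settle whether carry-over tracked by these means was a source. Carry-over that the means do not track, or that keeps a gene from being called, was not tested. The AS3h condition may account for the difference. Differences in handling between the groups, including the hour of sampling, stay open, since the labels give no batch and no time of sampling.

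Ccr3 was higher in AS3h, which might come from more microglia, from blood, or from a single library. The microglial markers had a mean log2 fold change of -0.24 (limma's fry, adjusted p = 0.0232), so marker RNA gave no sign of more microglia. Camera with an estimated correlation did not call the list (adjusted p = 0.367). Bulk marker RNA cannot separate cell number from expression per cell, so microglial number was not settled. No single library carried the Ccr3 rise: its lowest log2 fold change with 1 library left out was 0.92. With the blood marker mean as a covariate Ccr3 was at 0.77 ± 0.33 (SE; 95% interval 0.058 to 1.48; adjusted p = 0.192), against 1.15 without (adjusted p over the alternatives of the main fit 0.0149 to 0.206). The wide interval leaves blood and a change in brain cells in AS3h unable to be told apart here.

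Choroid plexus markers were high in AS3h 5 and, less so, AS3h 4, which may be tissue carried over in dissection. In AS3h 5, Ttr stood at 15.90 (log2) against an NC median of 7.78, and Kl at 10.86 against 4.43. The first test asked whether the 5 highest markers exceeded the NC median by like amounts; their log2 excess had an SD of 2.02, above the bound of 1.5 set for 1 source. That bound was wrong, since a log2 excess also depends on the baseline and Enpp2 already stood at 11.75 in NC, so the test decides nothing and no other was put in its place. The list means of AS3h 1 (5.08), AS3h 3 (5.55) and AS3h 6 (4.92) lay in the NC range of 4.46 to 6.16, so the list mean did not rise in every AS3h library. AS3h 2 stood above that range at 6.46. The 1 called member, Kcne2, was higher in all 6 AS3h libraries than in any NC library. A smaller difference between the groups stays open: the list mean differed by 1.42 with all libraries (exact permutation p = 0.0996), by 0.74 without AS3h 5 (exact permutation p = 0.203) and by 0.32 without AS3h 4 and AS3h 5 (camera adjusted p = 0.148).

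Values set apart from the rest of their group are given next, each with its gap to the nearest library as a share of the group's range. AS3h 2 was highest for the list means of chemokines (mean log2 value 5.96, share 0.691), reactive astrocyte genes (7.71, 0.632), antioxidant genes (9.95, 0.718) and mural and fibroblast markers (10.41, 0.647). NC 4 was highest for the mean of neighbouring region markers (8.47, 0.646) and lowest for Tbr1 (8.86, 0.751), Rbm3 (11.40, 0.672) and Abcc9 (7.98, 0.758). NC 2 was highest for Slco1a4 (11.77, 0.731) and Eng (9.40, 0.71). NC 1 was lowest for Klf8 (4.44, 0.665) and for the mean of cytokines and NF-kB targets (5.92, 0.744), NC 3 for Per2 (10.41, 0.747), and AS3h 4 for Arg1 (7.89, 0.732). Serpina16 was above 0 in NC 4 alone among NC libraries, Prr30 in NC 5 alone, and the smaller Rpl13a row in AS3h 1 alone among AS3h libraries, each with a share of 1.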

How the results depend on the processing

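Other library factors, the omission of AS3h 4 and AS3h 5 and the covariates were chosen after the data were seen; the rest were planned. The planned runs in edgeR and DESeq2 were left out once the fallback for normalised values was chosen, although the recovered reads would have allowed them. Between 1489 (no filter) and 2300 (limma-voom) genes passed under the other factors, filters, pseudocount and voom, and Ccr3 kept its direction and call there. The other library factors moved the median of all genes by under 0.01. Without AS3h 4 and AS3h 5, 861 genes passed (455 higher, 406 lower). With the blood and choroid plexus covariates, 758 passed (439 higher, 319 lower), 10 lists were called, Ccr3 was at 0.84 (adjusted p = 0.206), and the oligodendrocyte list reversed to a mean of -0.17 (adjusted p = 0.0145); the cause was not tested. In camera, an estimated correlation left 0 lists (3 at an unadjusted p under 0.05), and fry called 6: 4 of camera's 6, with hypoxia and heat shock in place of the choroid plexus and mitochondrial lists (fry adjusted p = 0.222 each). An unadjusted p under 0.05 with 1.5-fold gave 858 genes (418 higher, 440 lower), an adjusted p under 0.05 with 2-fold 133 (92 higher, 41 lower), and an adjusted p under 0.10 gave 2835 (1511 higher, 1324 lower).

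Leaving out each library in turn (minimum in 5 libraries) gave 1029 to 1760 genes, 589 to 968 higher and 440 to 819 lower, 6 to 8 lists, and a Ccr3 log2 fold change of 0.92 to 1.29 (adjusted p = 0.0156 to 0.0438). Without NC 2, 1029 genes passed and without AS3h 4, 1091. Of the 74 other named genes past the threshold, 23 lost their call in at least 1 such omission. With the replicate number as a block, 1296 genes passed (691 higher, 605 lower), 8 lists were called and Ccr3 had an adjusted p of 0.0212. The values gave no sign that the numbers pair the libraries. Same-numbered deviations correlated at -0.062 to 0.071, and 1 of 6 NC libraries correlated best with its own number. Weak correlations cannot exclude a pairing. Depth limits the genes with few reads, such as Serpina16 and Prr30 with 5 NC reads each.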

Other observations

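Both gene groups in this part were drawn up after single members had been seen among the changed genes. Those members were left out, and the tests were set before the rest of each group was looked at. The p values of both groups are unadjusted, unlike those printed for the 28 fixed lists. Unadjusted, camera with an estimated correlation gave p = 0.0178 for the immediate early list and 0.0125 for the clock list. Neither group was run with the covariates or with any library left out.

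Cholesterol and fatty acid synthesis genes were higher in AS3h. Of 29 tested, without Insig1 and Dhcr7, which led to the list, 13 rose, 0 fell and 16 did not pass. Scd, encoding stearoyl-CoA desaturase (log2FC 0.64 ± 0.084, adjusted p = 0.000467), Mvd, for mevalonate decarboxylation (log2FC 0.60 ± 0.08, adjusted p = 0.00045) and Hsd17b7 (log2FC 0.58 ± 0.079, adjusted p = 0.00057) were among them. The mean log2 fold change of the list was 0.21 (fry p = 3.12e-05; camera p = 2.49e-11, and p = 0.00679 with an estimated correlation). As a hypothesis, sterol synthesis may be raised as a programme in AS3h hippocampus; which cells carry it was not tested.

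Splicing regulator genes leaned lower. Of 37 tested, without Rsrp1, Luc7l3, Nxf1 and Ttc14, 8 fell, 2 rose and 27 did not pass. Clk1, a kinase of splicing factors (log2FC -0.70 ± 0.14, adjusted p = 0.00926), Tra2a (log2FC -0.47 ± 0.067, adjusted p = 0.000726), Sfpq (log2FC -0.41 ± 0.059, adjusted p = 0.000726) and Rbm5 (log2FC -0.40 ± 0.056, adjusted p = 0.000576) were among those that fell, and Srsf3 (log2FC 0.29 ± 0.073, adjusted p = 0.0233) was among those that rose. The mean log2 fold change was -0.11 (fry p = 0.00281; camera p = 0.00011, and p = 0.0874 with an estimated correlation). A joint decrease is a hypothesis that may hold for part of the group only.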
